A study of Homo sapiens with 8 samples.

How the data were processed

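Gene expression was measured by RNA sequencing in BEAS-2B cells, an immortalised human bronchial epithelial line, after 4 h of exposure. The 8 libraries fall into 4 groups of 2 by the labels: Mock (PBS), FBG (fibrinogen), FCP (Der m 1-derived FCP) and aC (the fibrinogen αC domain), the treatments at 4 ng/µl. The series title words the αC domain as derived from the allergen, and its preparation is not given in the sources used here. Per the labels' protocols, RNA was isolated with a column kit, messenger RNA was enriched by a method that is not given in the sources used here, and complementary DNA was made with random primers. The labels number biological replicates 1 and 2 in each group and do not say whether equal numbers share a culture or a day.

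The deposited values are raw counts of read pairs per gene, made by the authors with featureCounts in paired-end mode over exons summed by gene, with no strand option and no multi-mapping option, per the file headers. The headers give featureCounts 1.6.0 and the submitters' processing notes 1.6.2. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 2.2.1 and SAMtools 1.9 were also used, with no role or order given, and the build was GRCh38.p14. Each file lists 50006 genes, of which 6499 lie on alternate loci or patches, so 9927 entries belong to genes with a copy and 3428 of these lie on the primary assembly. Reads of such a gene can be split between its copies or, without a multi-mapping option, go uncounted. ZYX had 3007 and 46 counts in the 2 Mock libraries, and its copy had 5 and 3. Adding copies therefore does not restore the level, and counts near 0 do not show that such a gene is absent. Reads of a gene and its antisense partner cannot be told apart without strand. Values of genes with copies, close relatives, pseudogenes or overlapping neighbours are therefore uncertain. Coordinates are those of the deposited files, in GRCh38.p14.

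Depth differed by group: 15137196 to 22258791 counts per library. The lowest level that 3 counts allow was 0.181 CPM in Mock, 0.198 in FBG, 0.138 in FCP and 0.135 in aC. Intervals and floors cover counting error only. The standard error of the fitted fold change lay below the counting error of the summed counts for 45.1% of genes in FBG against Mock, 27.4% in FCP against Mock, 26.3% in aC against Mock, 23.1% in FCP against FBG, 21.6% in aC against FBG and 6.5% in aC against FCP, so the errors printed for those genes are too small. Called genes whose log2 fold change had a 95% counting interval that included 0 numbered 7, 2, 1, 1, 0 and 0 in the same order.

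Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr by group) in R 4.3.3, with all 8 libraries in 1 fit, which leaves 4 residual degrees of freedom. Of the genes, 16307 passed the filter. The common biological coefficient of variation was 0.102 and the trended values ran from 0.0099 to 0.261 with a median of 0.126. Fold changes are log2 values from that fit. Their standard errors are the absolute fold change divided by the square root of the quasi-likelihood F statistic, so they are approximate. The P values were adjusted by Benjamini-Hochberg within each of the 6 comparisons, with a gene called under 0.05. Log2 CPM used a prior count of 2. Where a group had 1 to 3 counts in all, the ratio of summed counts is given with its 95% counting interval.

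Gene lists were tested with camera in limma 3.58.1 on the log2 CPM, with a preset correlation of 0.01 and again with an estimated correlation, over lists with at least 5 tested genes and Benjamini-Hochberg over lists. At the preset correlation the degrees of freedom come from the number of genes, with an estimated correlation from the 4 residual ones. A call lost with an estimated correlation therefore mixes correlation between genes with the low power of 2 libraries per group. Fry was run beside it, which tests whether a list moves on balance 1 way and does not compare it with other genes. The 33 lists hold 822 genes, 809 matched by symbol and 13 by mitochondrial coordinates. They are integrin subunits, focal adhesion components, adherens junction components, protocadherins, tight junction components, desmosome and hemidesmosome components, immunoglobulin-family and other adhesion receptors, extracellular matrix, matrix proteases and inhibitors, plasminogen and coagulation system (the 10 adhesion lists), NF-kB and inflammatory targets, type 2 and epithelial alarmin mediators, Toll-like and innate receptors, interferon-stimulated genes, immediate early genes, TGF-beta and mesenchymal transition, YAP and serum response factor targets, oxidative stress and NRF2 targets, heat shock and proteotoxic stress, unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, p53 targets, S phase and mitosis, metallothioneins and metal response, glucocorticoid targets, airway epithelial and keratin markers, fibroblast markers, blood and immune cell markers, endothelial markers, mitochondrially encoded messenger RNAs, replication-dependent histone messenger RNAs and cytosolic ribosomal proteins. Some genes stand in several lists (CCN1 and CCN2 in extracellular matrix and YAP targets, COL1A1 in extracellular matrix and fibroblast markers, ICAM1 in adhesion receptors and NF-kB targets), so lists are not independent. List medians with genes near the floor set at their bound moved by at most 0.45 in FBG against Mock, 0.16 in FCP against Mock, 0.04 in aC against Mock, 0.48 in FCP against FBG, 0.51 in aC against FBG and 0.01 in aC against FCP.

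The design, the lists, the 21 preset genes, the rule for named genes and most alternatives were chosen before the data were examined. The rule names, per comparison, the 8 risen and 8 fallen genes with the smallest p among those with a mean of at least 50 counts, up to 4 members of each called list, 2 members of each adhesion list against Mock, and the preset genes. The text names a part of these from the top of each group, and some genes are not reported here. Alternatives were DESeq2 1.42.0 size factors and Wald test, library size only, no filter, a stricter filter of 10 CPM in 2 libraries, the replicate number as a block, only the libraries of both groups, each library left out in turn, other thresholds, and estimated correlations. Leaving out genes with copies, removing trends and thinning to equal depth were added after the data were seen.

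GC content and length trends were removed per library with mgcv 1.9.3, with values from GENCODE 29 transcripts, for 97.9% of genes with a mean of at least 50 counts. Mitochondrial genes had no such value and left that fit. Chromosome medians used 10674 autosomal genes without copies and 1000 bootstrap draws. Unchanged groups sharing the Mock libraries were simulated 50 times. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

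The fit was tested on simulated data with 200 changed genes per comparison. In simulated FBG against Mock (15868 genes) it recovered 34% of genes changed by 0.25, 70% at 0.5, 76% at 1 and 100% at 2 on the log2 scale, and in simulated aC against FCP (15873 genes) 22%, 66%, 88% and 96%. False calls were 9.68% and 12.3% of the calls in these simulations, above the nominal 5%, and 9.27%, 12.3%, 12.1% and 8.09% in simulated FCP against Mock, aC against Mock, FCP against FBG and aC against FBG. A simulated list shift of 0.5 in aC against FCP was called, with 0 of the other lists. In a simulated GC trend the correction took the correlation of fold changes with GC content from 0.736 to 0.012 and returned 0.38 for a chromosome shifted by 0.4.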

Results

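RNA from BEAS-2B cells, an immortalised human bronchial epithelial line grown here in serum-free LHC-9 medium, was sequenced after 4 h of exposure to one of 3 fibrinogen-related preparations or to buffer. The series asks which adhesion-related transcripts change. The groups were Mock (PBS), FBG (fibrinogen), FCP and aC (the fibrinogen αC domain), the last 3 at 4 ng/µl. FCP is a Der m 1-derived preparation whose abbreviation the labels do not expand. The sample labels call aC a domain of fibrinogen while the series title words it as derived from the allergen, and how it was made is not given in the sources used here. Der m 1 is the group 1 allergen of the house dust mite Dermatophagoides microceras. Each group had 2 libraries, 8 in all. Total counts were 16553366 and 16561302 in the Mock libraries, 15137196 and 15144403 in FBG, 21715092 and 21680688 in FCP and 22258791 and 22248780 in aC. Genes with at least 1 count numbered 20694 to 20747 in Mock, 21417 to 21533 in FBG, 24283 to 24315 in FCP and 24556 to 24602 in aC.

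KRT5 and COL1A1 separated the FCP and aC libraries from the Mock and FBG libraries. KRT5, a keratin of basal epithelial cells (chromosome 12, 52514575 to 52520394), had a mean level of 2.03 TMM-scaled CPM in Mock (SD 0.331, n = 2), 7.28 in FBG (SD 0.475), 1581 in FCP (SD 13.3) and 1603 in aC (SD 45.9). COL1A1, a chain of type I collagen (chromosome 17, 50184101 to 50201631), went the other way, from 2155 in Mock (SD 17) and 1089 in FBG (SD 2.77) to 173 in FCP (SD 0.0716) and 184 in aC (SD 1.9). The first principal component held 75.4% of the variance and placed Mock at -88.3 and -87.8, FBG at -63.9 and -62.9, FCP at 72.6 and 73.3 and aC at 78.3 and 78.8. The second held 9% and lay mainly between Mock (32.5 and 35.3) and FBG (-40.7 and -39). Mitochondrial genes took 4.07% to 4.09% of counts in Mock and 4.24% to 4.27% in FBG. They took 4.45% to 4.47% in FCP and 4.13% to 4.15% in aC. The 10 most abundant genes took 5.5% to 6% of each library. Other shares also moved with the groups. Mitochondrial ribosomal RNA took 0.269% in Mock, 0.465% to 0.47% in FBG, 0.461% to 0.465% in FCP and 0.399% to 0.401% in aC. Long non-coding RNA genes took 0.635% to 0.636% in Mock, 0.711% to 0.715% in FBG, 0.89% to 0.893% in FCP and 0.926% to 0.928% in aC.

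**Figure D1:**
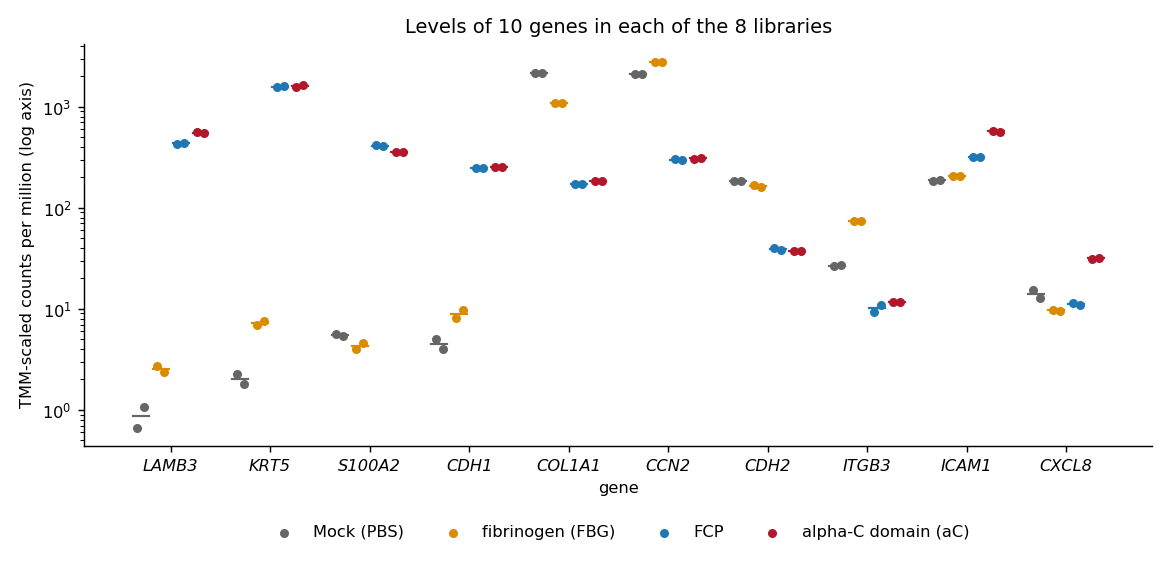
Normalised CPM after TMM scaling (vertical log axis) of 10 genes in each of the 8 libraries. Points are libraries, coloured by group, and short bars are means of 2 libraries. KRT5 lies near 1581 and 1603 in FCP and aC against 2.03 in Mock, COL1A1 near 173 and 184 against 2155, and ICAM1 and CXCL8 are highest in aC.

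The libraries of a pair lay close together. Their totals differed by 0.045% to 0.159%, and over genes without a second copy in the annotation the counts of a pair differed by 1.27 to 1.37 times the counting variance, slightly above the value of about 1 for a single library sequenced again. This excess does not tell separate cultures from separate library preparations. Totals of a pair differed by 1.4, 1.3, 5.2 and 1.5 counting standard deviations in Mock, FBG, FCP and aC. Each library was kept as a sample of its own (n = 2 per group) because the labels number it as a biological replicate. Nothing in the labels says how far apart the cultures of a pair were, so the single-gene p-values below measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation judge a list against the spread over genes. Small ones therefore do not measure agreement between libraries. Genes that are also listed on an alternate locus were far noisier, at 57.9 to 79.7 times the counting variance. The focal adhesion gene ZYX had 3007 and 46 counts in the 2 Mock libraries and CTTN 807 and 87, so values of such genes are uncertain.

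Genes on chromosome 9 were higher as a group in FCP and aC than in Mock and FBG. After removal of GC content and length trends, and relative to all autosomal genes, the median log2 fold change of the 479 chromosome 9 genes was 0.47 in FCP against Mock (95% bootstrap interval 0.4 to 0.52, with 81.8% of the genes above 0) and 0.46 in aC against Mock (0.41 to 0.52). Chromosome 6 (501 genes) had a median of 0.3 in FCP against Mock (0.26 to 0.36). On chromosome 18 the 44 genes between 0.2 and 14.1 Mb had a median of 0.81 (0.69 to 1.01), against 0.08 for the 125 genes from 20.9 to 80.2 Mb. In FBG against Mock no autosome lay further than 0.05 from 0, and in aC against FCP none further than 0.02. These shifts go with every comparison below that sets FCP or aC against Mock or FBG. Those comparisons therefore cannot tell a response to FCP or aC from another difference along this division. In them, risen and fallen mean higher and lower in the FCP or aC libraries.

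**Figure D2:**
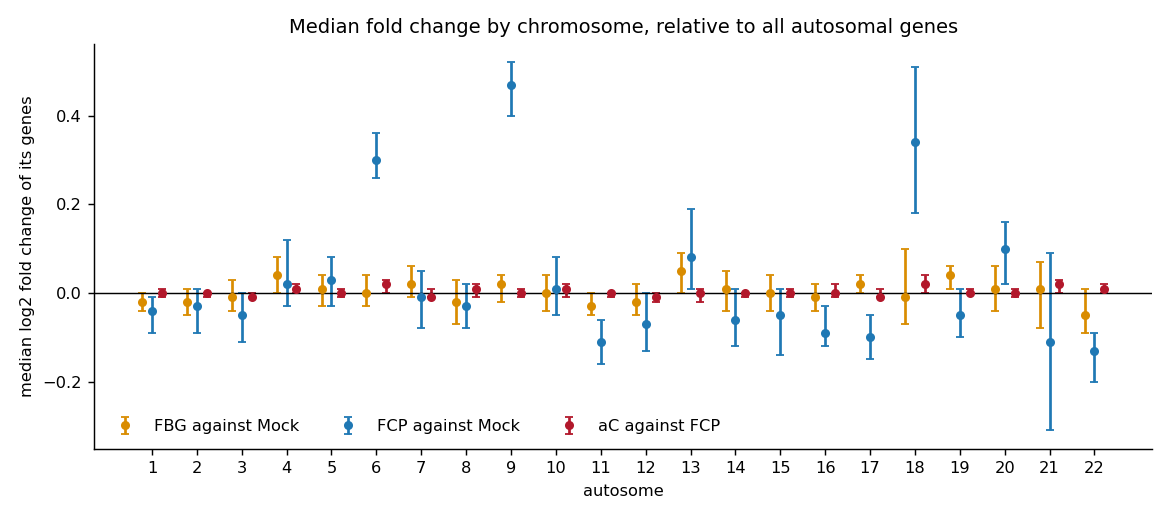
Median log2 fold change (vertical axis) of the genes of each autosome (horizontal axis) relative to all autosomal genes, after removal of GC content and length trends, in 3 comparisons. Bars are 95% bootstrap intervals over genes. Chromosomes 9, 18 and 6 stand at 0.47, 0.34 and 0.3 in FCP against Mock, while FBG against Mock and aC against FCP stay within 0.05 and 0.02 of 0.

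The first comparison, FBG against Mock, asked whether intact fibrinogen changes expression. Its fold changes followed transcript GC content and length, with Spearman correlations across genes of -0.52 and 0.23. The values given here are without removal of these trends. Among the risen genes with the smallest p-values, MKI67, a proliferation marker, rose by 1.37 ± 0.02 (log2, ± SE, n = 2 against 2), CENPF, a kinetochore protein, by 1.6 ± 0.03, and the nuclear pore genes RANBP2 and TPR by 1.66 ± 0.03 and 1.63 ± 0.03. The list of S phase and mitosis genes as a whole was not called, with 8 risen and 17 fallen of 30 (25 adjusted over the list alone), a median of -0.08, a mean of 0.01 and a camera adjusted p = 0.24. COL1A1 fell by 0.99 ± 0.01 and the matrix gene THBS2 fell by 1.67 ± 0.03. Of the matricellular pair CCN1 and CCN2, CCN1 fell by 0.26 ± 0.003 and CCN2 rose by 0.37 ± 0.003. PPME1, a phosphatase methylesterase, rose by 1.02 ± 0.02, KTN1 by 1.41 ± 0.03 and MACF1, a cytoskeletal linker, by 0.9 ± 0.02. The chromatin protein HMGA1 (-0.97 ± 0.02), the long non-coding RNA LINC03061 (-1.32 ± 0.02), the endoplasmic reticulum chaperone CALR (-0.24 ± 0.004) and the transketolase gene TKT (-0.88 ± 0.02) fell.

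Adhesion genes moved in both directions in FBG against Mock. Among integrin subunits 9 rose and 4 fell of 19 tested (13 adjusted over the list alone). The smallest p-values were those of ITGB3, the β3 subunit of the vitronectin and fibrinogen receptor (1.47 ± 0.07), and ITGA1 (1.06 ± 0.09). The junction genes DST (1.42 ± 0.04) and DSP (0.75 ± 0.03) rose, with 8 risen and 3 fallen of 17 desmosome and hemidesmosome genes (11 adjusted over the list alone). The hyaluronan receptor CD44 fell by 1.23 ± 0.03, the syndecan SDC4 by 0.63 ± 0.02, TIMP1, an inhibitor of matrix proteases, by 1.05 ± 0.02, and PLAT, tissue plasminogen activator, by 1.4 ± 0.05. Other members with the smallest p-values were LPP (0.84 ± 0.03) and PXN (-0.51 ± 0.03) of focal adhesions, FAT4 (1.04 ± 0.06), a protocadherin-list member, and CLDN1 (-0.47 ± 0.04) of tight junctions. None of the 10 adhesion lists was called as a group against all other genes (camera, smallest adjusted p = 0.0679, for desmosome and hemidesmosome genes). At the preset correlation the desmosome and hemidesmosome list was called as higher with no filter (0.0273), without Mock replicate 2 (0.0226) and without FBG replicate 2 (0.00904).

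The cholesterol and fatty acid synthesis list was called lower in FBG against Mock at the preset correlation. Of its 27 genes 21 fell and 1 rose in FBG (22 adjusted over the list alone; camera adjusted p = 4.82e-11, and adjusted p = 0.175 with an estimated correlation). The transcription factor gene SREBF1 was at -1.41 ± 0.03 and the desaturase gene FADS2 at -0.83 ± 0.02. Cytosolic ribosomal protein genes fell in 65 of 75 cases by smaller amounts (66 adjusted over the list alone), such as RPSA by 0.46 ± 0.01 and RPL13 by 0.44 ± 0.02 (camera adjusted p = 9.78e-21, and adjusted p = 0.203 with an estimated correlation). These genes have processed copies elsewhere in the genome, so single values are uncertain. Among hypoxia and glycolysis genes 16 fell and 1 rose of 22 (18 adjusted over the list alone), for example PGK1 by 0.5 ± 0.02 and TPI1 by 0.44 ± 0.02 (camera adjusted p = 4.76e-05, and adjusted p = 0.175 with an estimated correlation). Mitochondrially encoded messenger RNAs fell in 9 of 13 cases and rose in 2 (13 adjusted over the list alone; camera adjusted p = 0.0345, and adjusted p = 0.462 with an estimated correlation). These 13 genes had no GC value, so the fit without GC content and length trends does not test them. Their median was -0.13, but -0.01 with library size only as the scaling, so most of their fall depends on the TMM scaling.

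In all, 8226 of 16307 tested genes were called in FBG against Mock (edgeR, adjusted p under the threshold), 3941 risen and 4285 fallen, and 866 rose and 259 fell at least 2-fold. With GC content and length trends removed, over genes with a GC value, 6890 were called, 3010 risen and 3880 fallen. These kept 63.6% of the 8226 calls, and 573 rose and 210 fell at least 2-fold. Of the 20 preset adhesion and inflammation genes tested, 18 were called (18 adjusted over the list alone), 9 in each direction. Beside those above, CDH1, encoding E-cadherin, rose by 1 ± 0.11 and ITGAV by 0.44 ± 0.04, while the urokinase gene PLAU fell by 0.86 ± 0.06, ITGA5 by 0.38 ± 0.04 and the chemokine gene CXCL8 by 0.55 ± 0.1. ITGA2 (0.48 ± 0.1), ICAM1 (0.14 ± 0.02), the endotoxin receptor gene TLR4 (0.24 ± 0.04), the protease receptor gene F2RL1 (0.8 ± 0.16) and ITGB1 (0.06 ± 0.01) rose. IL6 (-0.78 ± 0.23), PLAUR (-0.38 ± 0.14), CDH2 (-0.15 ± 0.03) and the fibronectin gene FN1 (-0.08 ± 0.004) fell. CD14 (-0.34 ± 0.29, adjusted p = 0.347) and CCL20 (0.49 ± 1.3, adjusted p = 0.799) were not called. ITGB6 had 17 counts in FBG and 2 in Mock, a ratio of 8.59 (95% counting interval 2.04 to 76.7). Fold changes in this comparison followed transcript GC content, with a Spearman correlation across genes of -0.52, and length, with 0.23, and genes are not independent replicates. Among genes with a mean of at least 50 counts, those risen at least 2-fold had a median GC content of 40.8% and length of 5579. The medians were 53.4% and 3765 for those fallen at least 2-fold and 47.7% and 3807 for all. With GC content and length trends removed ITGB1 (-0.2) and TLR4 (-0.25) were lower instead, and ITGA2 (0.16), ITGAV (0.05) and PLAUR (-0.15) were not called. The calls of IL6, ITGB6 and PLAUR ended without FBG replicate 1 (-0.37, 1.92 and -0.17) and without Mock replicate 1 (-0.87, 2.98 and -0.21). Without Mock replicate 2 those of IL6 (-0.69), ITGB6 (2.98) and ITGA2 (0.33) ended and CCL20 was called at 5.26. By the DESeq2 Wald test ITGB1 (0.03), IL6 (-0.81) and PLAUR (-0.4) were not called, and with library size only FN1 turned to 0.03 and CDH2 (-0.04), IL6 (-0.67) and PLAUR (-0.26) were not called. Scaling by library size only moved the median fold change of all genes from 0.02 to 0.13 here, from 0.06 to 0.28 in FCP against Mock and from 0.06 to 0.29 in aC against Mock, and turned the split in FBG against Mock to 5186 risen and 3010 fallen.

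The second comparison, FCP against Mock, set the Der m 1-derived preparation against buffer, along the division of chromosome medians described above. Among the risen genes with the smallest p-values, LAMB3, a laminin chain of epithelial basement membranes (chromosome 1, 209614870 to 209652425), was higher in FCP by 8.95 ± 0.06 on the log2 scale (n = 2 against 2), S100A2 by 6.21 ± 0.04, the tensin gene TNS4 by 6.86 ± 0.04 and COL7A1, the collagen of anchoring fibrils, by 3.62 ± 0.03. C3, a complement component, rose by 3.28 ± 0.02 and the protease inhibitor gene SPINT2 by 3.87 ± 0.04. Of the fallen genes with the smallest p-values, CCN1 was lower by -2.14 ± 0.01, the chaperone gene CALR by -1.05 ± 0.004, COL1A1 by -3.64 ± 0.02, ABI3BP by -5.83 ± 0.04, the growth factor binding protein gene IGFBP3 by -2.88 ± 0.02 and STC2 by -2.88 ± 0.02. CCN2 was lower by -2.82 ± 0.01 and the ribosomal protein gene RPL6 by -0.62 ± 0.004. The cyclin gene CCND2 had 13854 counts in FCP and 3 in Mock, a ratio of 3030 (95% counting interval 1030 to 14700).

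Cell-cell junction genes changed their members in FCP against Mock. CDH1 rose by 5.79 ± 0.06 (chromosome 16, 68737292 to 68835537) and CDH3, P-cadherin, by 4.09 ± 0.05, while CDH2, N-cadherin, fell by 2.24 ± 0.04. In the adherens junction list 8 genes rose and 5 fell of 16 (13 adjusted over the list alone; camera adjusted p = 0.213). Desmosome and hemidesmosome genes rose in 14 of 17 cases and fell in 3 (17 adjusted over the list alone), with a camera adjusted p = 6.63e-05, and adjusted p = 0.0686 with an estimated correlation. DST was at 3.1 ± 0.03 and DSP at 3.23 ± 0.02. In the tight junction list 7 rose and 2 fell of 14, 5 of them with annotated copies (8 adjusted over the list alone; camera adjusted p = 0.105). The smallest p-values were those of F11R at 1.51 ± 0.04 and MARVELD3 at 6.93 ± 0.19. Protocadherins rose in 4 and fell in 8 of 15 cases (12 adjusted over the list alone; camera adjusted p = 0.285), with PCDH19 at -3.87 ± 0.06. Among immunoglobulin-family and other adhesion receptors 9 rose and 7 fell of 17 (16 adjusted over the list alone; camera adjusted p = 0.572), and EPCAM, an epithelial adhesion molecule, rose by 5.81 ± 0.08.

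**Figure D3:**
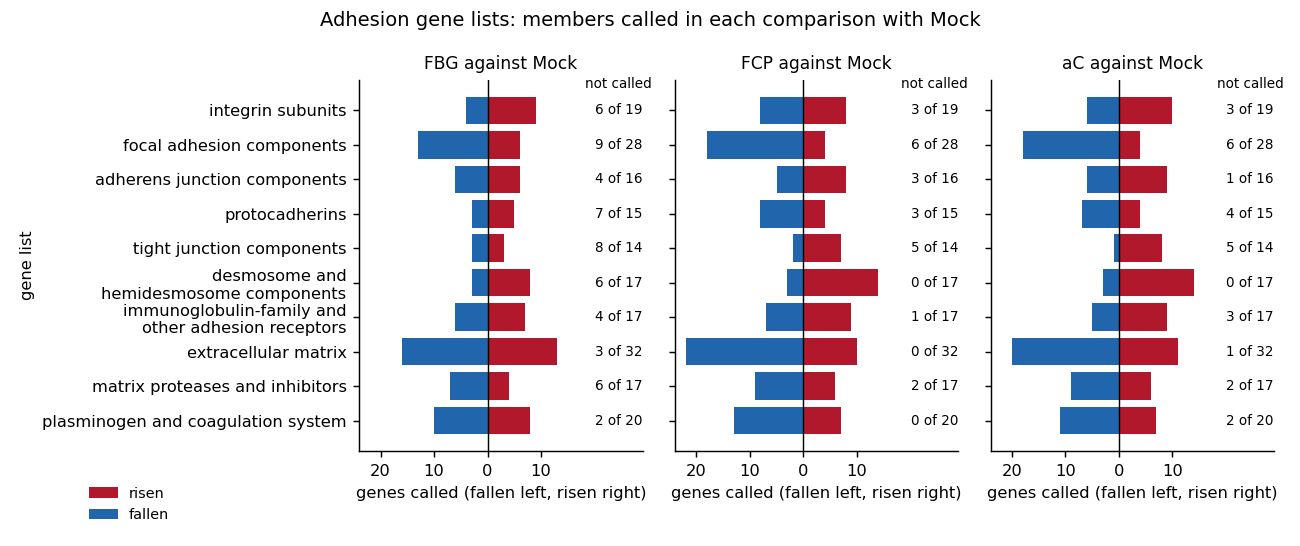
Numbers of genes that fell (left of 0) and rose (right of 0) in the 10 adhesion lists, in each treated group against Mock (edgeR, n = 2 libraries per group). The column at the right gives the members not called. Desmosome and hemidesmosome genes rose in 14 of 17 cases in FCP and in aC, and extracellular matrix genes fell in 22 and 20 of 32.

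Cell-matrix adhesion genes were split in FCP against Mock. Of the integrin subunits 8 rose and 8 fell of 19 (16 adjusted over the list alone; camera adjusted p = 0.572). Their median was -0.03 and their mean 0.51, and the median turned to 0.19 when only library size was used for scaling. ITGA2, a collagen receptor subunit, rose by 3.47 ± 0.08 and ITGA6, a laminin receptor subunit, by 2.15 ± 0.03, while ITGA11 (-3.75 ± 0.04) and ITGB3 (-1.4 ± 0.07) fell. ITGB6, a partner of ITGAV (1.04 ± 0.04), had 2894 counts in FCP and 2 in Mock, a ratio of 948 (95% counting interval 262 to 7830). Focal adhesion genes fell in 18 and rose in 4 of 28 cases (22 adjusted over the list alone), with a camera adjusted p = 0.00435, and adjusted p = 0.0844 with an estimated correlation. The kindlin genes went in opposite directions, FERMT2 at -1.43 ± 0.03 and FERMT1 at 3.44 ± 0.06, and 5 of the 28 genes have annotated copies. Extracellular matrix genes fell in 22 of 32 cases and rose in 10 (32 adjusted over the list alone; camera adjusted p = 0.00597, and adjusted p = 0.0844 with an estimated correlation). Matrix proteases and inhibitors rose in 6 and fell in 9 of 17 cases (15 adjusted over the list alone; camera adjusted p = 0.407), and the sign of their median turned with library size only. TIMP2 was at -1.41 ± 0.02 and TIMP1 at -1.81 ± 0.02. In the plasminogen and coagulation list 7 rose and 13 fell of 20 (20 adjusted over the list alone; camera adjusted p = 0.105), and the list was called as lower with no filter (adjusted p = 0.0145 at the preset correlation). The transglutaminase TGM2 was at -1.56 ± 0.02 and PLAU at 1.9 ± 0.05.

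Markers of cell identity moved with these genes. Airway epithelial and keratin markers rose in 15 of 18 cases and fell in 2 (17 adjusted over the list alone), with KRT5 at 9.6 ± 0.05 and KRT17 at 1.52 ± 0.02 (camera adjusted p = 2.39e-05, and adjusted p = 0.0527 with an estimated correlation). Fibroblast markers fell in 6 and rose in 2 of 9 cases (8 adjusted over the list alone), including THY1 by 1.79 ± 0.04 and COL1A2 by 3.47 ± 0.1 (camera adjusted p = 0.0329, and adjusted p = 0.255 with an estimated correlation). KRT17 has pseudogenes, so its value is uncertain. Only 4 endothelial markers of 12 were tested, too few for a list test, and all 4 rose at low counts: PECAM1, CDH5, KDR and ROBO4 by 1.98 ± 0.62, 2.38 ± 0.58, 1.42 ± 0.56 and 0.92 ± 0.25. Of the 4 blood and immune markers tested, out of 21, CSF1R rose (2.82 ± 0.6) and CD68 (-1.33 ± 0.09) and CPA3 fell, CPA3 from 65 and 55 counts in the Mock libraries to 2 and 1 in FCP. These 7 genes were chosen after their values were seen. NF-kB and inflammatory targets rose in 25 of 34 cases and fell in 5 (32 adjusted over the list alone), with a camera adjusted p = 2.39e-05, and adjusted p = 0.0527 with an estimated correlation. The interleukin genes IL1A and IL1B were at 8.64 ± 0.13 and 8.55 ± 0.16 from 4 Mock counts each, and TNFAIP2 at 1.88 ± 0.03. The printed errors of IL1A and IL1B lie below the counting error of so few counts. Targets of YAP and serum response factor fell in 20 and rose in 5 of 25 cases (25 adjusted over the list alone), with FHL2 at -2.92 ± 0.03 and AXL at -1.21 ± 0.01 (camera adjusted p = 4.79e-05, and adjusted p = 0.0527 with an estimated correlation).

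Stress response, S phase and mitosis, ribosomal protein, cholesterol and fatty acid, hypoxia and mitochondrially encoded lists were called lower in FCP against Mock at the preset correlation. Genes of the unfolded protein and integrated stress response fell in 18 of 22 cases and rose in 2 (20 adjusted over the list alone), with PHGDH at -1.47 ± 0.02 (camera adjusted p = 6.03e-05, and adjusted p = 0.0527 with an estimated correlation). Genes of S phase and mitosis fell in 24 of 30 and rose in 5 (29 adjusted over the list alone), yet MKI67 rose by 1.75 ± 0.02 and CENPF by 2.13 ± 0.03 (camera adjusted p = 4.79e-05, and adjusted p = 0.0527 with an estimated correlation). Cytosolic ribosomal protein genes fell in 71 of 75 cases and rose in 1 (73 adjusted over the list alone), RPL28 by 1.19 ± 0.02 (camera adjusted p = 1.17e-21, and adjusted p = 0.0808 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 19 of 27 and rose in 4 (23 adjusted over the list alone; camera adjusted p = 0.000255, and adjusted p = 0.127 with an estimated correlation), hypoxia and glycolysis genes fell in 11 of 22 and rose in 5 (16 adjusted over the list alone; camera adjusted p = 0.03, and adjusted p = 0.183 with an estimated correlation), and mitochondrially encoded messenger RNAs fell in 11 of 13 and rose in 1 (12 adjusted over the list alone; camera adjusted p = 0.000351, and adjusted p = 0.225 with an estimated correlation). With GC content and length trends removed hypoxia and glycolysis genes were not called (adjusted p = 0.0996). The median of the mitochondrially encoded list was -0.26, but -0.04 with library size only as the scaling, so most of its fall depends on the TMM scaling.

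The remaining lists were not called in FCP against Mock. Interferon-stimulated genes had 15 risen and 9 fallen of 33, a camera adjusted p = 0.407 and 23 called adjusted over the list alone. In the same order, the values were 8 and 19 of 33, 0.0675 and 27 for immediate early genes and 9 and 11 of 23, 0.568 and 20 for TGF-beta and mesenchymal transition genes. Type 2 and epithelial alarmin mediators had 4 and 2 of 6, 0.407 and 6, with a median of 2.21 and a mean of -0.29, and Toll-like and innate receptors 6 and 3 of 15, 0.647 and 9. The values were 5 and 7 of 19, 0.572 and 12 for oxidative stress and NRF2 targets, 6 and 8 of 15, 0.407 and 14 for heat shock genes, whose median changed sign with library size only, and 11 and 7 of 20, 0.407 and 18 for p53 targets. They were 4 and 3 of 9, 0.746 and 7 for metallothioneins, 1 and 8 of 12, 0.0694 and 9 for glucocorticoid targets, and 5 and 2 of 16, 0.38 and 7 for replication-dependent histones, whose transcripts mostly lack a poly(A) tail. At the preset correlation glucocorticoid targets and immediate early genes were called as lower without Mock replicate 1 (0.0387 for each) and with no filter (0.00748 and 0.00665), and glucocorticoid targets with trends removed (0.0199, and adjusted p = 0.216 with an estimated correlation).

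In all, 11969 of 16307 genes were called in FCP against Mock, 6085 risen and 5884 fallen. At least 2-fold, 3208 rose and 1442 fell, and at least 16-fold, 438 rose and 93 fell. Scaling by library size only changed the split to 7679 risen and 4493 fallen, and removing GC content and length trends to 4914 risen and 5832 fallen. Fold changes had Spearman correlations across genes of -0.34 with GC content and 0.32 with length here. In aC against Mock these were -0.31 and 0.31. Of the 20 preset genes, 18 were called (18 adjusted over the list alone), 11 risen and 7 fallen. TLR4 fell by 1.3 ± 0.05, CXCL8 by 0.34 ± 0.09, CD44 by 0.49 ± 0.03 and ITGB1 by 0.35 ± 0.01. IL6 rose by 3.1 ± 0.17, CCL20 by 3.77 ± 0.91, F2RL1 by 1.19 ± 0.15, ICAM1 by 0.77 ± 0.02, PLAUR by 0.7 ± 0.13 and FN1 by 0.15 ± 0.002. The endotoxin co-receptor gene CD14 was not called (0.41 ± 0.27, adjusted p = 0.166), nor was ITGA5 (-0.03 ± 0.04, adjusted p = 0.503), and LY96 had 3 counts over the 8 libraries and was not tested. With GC content and length trends removed FN1 turned to -0.32 and CD14 was called at 0.83, and with library size only ITGA5 was called at 0.19 and CD14 at 0.63 and CXCL8 (-0.12) was not called. Calls that ended were CXCL8 without Mock replicate 1 (-0.21), CCL20 without FCP replicate 1 or 2 (3.72 and 3.83), PECAM1 without Mock replicate 2 (1.57) or FCP replicate 2 (1.68), KDR without Mock replicate 1 or 2 (1.62 and 1.22) or FCP replicate 1 or 2 (1.37 and 1.47), and KDR (1.43) and ROBO4 (0.91) by DESeq2.

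The third comparison, aC against Mock, set the αC domain against buffer, along the same division of chromosome medians. LAMB3 (9.31 ± 0.06, n = 2 against 2), C3 (3.64 ± 0.02), TNS4 (6.89 ± 0.04) and S100A2 (6.02 ± 0.04) rose here too. TNFAIP2, an NF-kB-induced gene, rose by 3.35 ± 0.03, COL7A1 by 3.81 ± 0.03 and the matrix glycoprotein gene TNC by 5.36 ± 0.05. CCN1 (-2.25 ± 0.01), CALR (-1.12 ± 0.005), COL1A1 (-3.55 ± 0.02), IGFBP3 (-3.22 ± 0.02), RPL6 (-0.66 ± 0.004) and CCN2 (-2.77 ± 0.01) fell. CDH1 rose by 5.82 ± 0.06 and CDH2 fell by 2.28 ± 0.04. ITGB6 had 3986 counts in aC and 2 in Mock, a ratio of 1260 (95% counting interval 350 to 10400), and CCND2 had 11551 and 3, a ratio of 2440 (836 to 11800). TP63, a transcription factor of basal epithelium, had 5147 and 2, a ratio of 1630 (452 to 13500).

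NF-kB and inflammatory targets rose in 31 of 34 cases and fell in 1 (32 adjusted over the list alone), with SOD2 at 2.34 ± 0.02 and the leukocyte adhesion receptor gene ICAM1 at 1.62 ± 0.02 (camera adjusted p = 7.14e-10, and adjusted p = 0.0431 with an estimated correlation). Interferon-stimulated genes rose in 19 and fell in 6 of 33 cases (25 adjusted over the list alone), for example RIGI by 2.95 ± 0.09 and SAMD9 by 2.63 ± 0.1 (camera adjusted p = 0.0193, and adjusted p = 0.108 with an estimated correlation). Desmosome and hemidesmosome genes rose in 14 and fell in 3 of 17 cases (17 adjusted over the list alone; camera adjusted p = 7.62e-05, and adjusted p = 0.0719 with an estimated correlation). Tight junction genes rose in 8 of 14 and fell in 1 (9 adjusted over the list alone), with F11R at 1.54 ± 0.04 and MARVELD3 at 6.95 ± 0.19 (camera adjusted p = 0.0193, and adjusted p = 0.124 with an estimated correlation). Focal adhesion genes fell in 18 of 28 and rose in 4 (22 adjusted over the list alone; camera adjusted p = 0.00467, and adjusted p = 0.0901 with an estimated correlation), and extracellular matrix genes fell in 20 of 32 and rose in 11 (31 adjusted over the list alone; camera adjusted p = 0.0173, and adjusted p = 0.108 with an estimated correlation). Integrin subunits rose in 10 and fell in 6 of 19 cases (16 adjusted over the list alone; camera adjusted p = 0.372), with ITGA2 at 3.55 ± 0.08, ITGAV at 1.26 ± 0.04 and ITGB3 at -1.18 ± 0.07.

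Airway epithelial and keratin markers rose in 16 and fell in 2 of 18 cases (18 adjusted over the list alone; camera adjusted p = 1.72e-05, and adjusted p = 0.0431 with an estimated correlation). Targets of YAP and serum response factor fell in 20 of 25 and rose in 5 (25 adjusted over the list alone; camera adjusted p = 1.72e-05, and adjusted p = 0.0431 with an estimated correlation). Stress response genes fell in 19 of 22 (21 adjusted over the list alone) and genes of S phase and mitosis in 25 of 30 (30 adjusted over the list alone), each with a camera adjusted p = 1.72e-05, and adjusted p = 0.0431 with an estimated correlation. Ribosomal protein genes (72 of 75 fallen), cholesterol and fatty acid genes (20 of 27), hypoxia and glycolysis genes (12 of 22), mitochondrially encoded messenger RNAs (12 of 13) and fibroblast markers (7 of 9) were also called lower. With an estimated correlation their adjusted p values were 0.0828, 0.108, 0.18, 0.144 and 0.249. With GC content and length trends removed hypoxia and glycolysis genes were not called (adjusted p = 0.114), and with an estimated correlation only NF-kB targets stayed called (adjusted p = 0.0319), while airway, YAP and S phase lists were each at adjusted p = 0.0714 and stress response genes at adjusted p = 0.101. In all, 12183 genes were called in aC against Mock, 6199 risen and 5984 fallen, or 7782 and 4489 with library size only as the scaling and 4979 and 5938 with trends removed, and 3381 rose and 1461 fell at least 2-fold. Of the 20 preset genes 19 were called (19 adjusted over the list alone), among them CXCL8 at 1.17 ± 0.09, IL6 at 4.1 ± 0.17, CCL20 at 5.72 ± 0.86, PLAU at 2.22 ± 0.05 and TLR4 at -1.37 ± 0.05. CD14 was not called (0.39 ± 0.27, adjusted p = 0.186), but was at 0.62 with library size only and at 0.77 with GC content and length trends removed.

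The treatments were also compared with intact fibrinogen. In FCP against FBG the genes with the smallest p-values were TNS4 (5.64 ± 0.04), LAMB3 (7.42 ± 0.05), C3 (3.34 ± 0.02) and S100A2 (6.58 ± 0.05) among the risen and CCN1 (-1.88 ± 0.01), CCN2 (-3.2 ± 0.01), CALR (-0.81 ± 0.01) and COL1A1 (-2.66 ± 0.02) among the fallen. ITGB3 was lower by -2.87 ± 0.07 and CD44 higher by 0.74 ± 0.03. In aC against FBG, C3 (3.7 ± 0.02), LAMB3 (7.77 ± 0.05), TNS4 (5.67 ± 0.04) and S100A2 (6.39 ± 0.05) rose and CCN1 (-1.99 ± 0.01), CCN2 (-3.15 ± 0.01), CALR (-0.88 ± 0.01) and PPME1 (-2.79 ± 0.02) fell. In FCP against FBG 10888 genes were called, 5319 risen and 5569 fallen, and in aC against FBG 11139, 5511 risen and 5628 fallen. The majority was risen with DESeq2 size factors (5488 and 5346 in FCP, 5681 and 5458 in aC), with no filter (5739 and 5410, 5983 and 5549), with the stricter filter (3964 and 3951, 4022 and 3982) and with library size only (6343 and 4598, 6538 and 4673), which moved the median of all genes from 0.02 to 0.12 and 0.14. Of the 20 preset genes 19 were called in each (20 and 19 adjusted over the list alone), with CXCL8 not called in FCP (0.21 ± 0.1, adjusted p = 0.0708). CXCL8 was called there with DESeq2 size factors (0.23), library size only (0.32) and trends removed (0.35). NF-kB targets rose in 29 of 34 cases in FCP (32 adjusted over the list alone; camera adjusted p = 8.09e-09, and adjusted p = 0.0323 with an estimated correlation) and in 32 of 34 in aC (32 adjusted over the list alone; camera adjusted p = 6.91e-14, and adjusted p = 0.0256 with an estimated correlation). Of the lists called, 5 in each comparison remained called with an estimated correlation, the NF-kB targets and airway markers as risen and the YAP, stress response and S phase lists as fallen. With trends removed as well, only the NF-kB and YAP lists stayed called with an estimated correlation, and the airway, stress response and S phase lists were at adjusted p = 0.0504, 0.0782 and 0.0782 in FCP and 0.0527, 0.072 and 0.0527 in aC. Cholesterol and fatty acid genes, lower in FBG than in Mock, were higher in FCP than in FBG in 15 of 27 cases and lower in 6 (21 adjusted over the list alone; camera adjusted p = 0.0242, and adjusted p = 0.233 with an estimated correlation). SREBF1 was at 1.12 ± 0.03. In aC against FBG 13 of the 27 rose and 8 fell (21 adjusted over the list alone), and the list was not called (camera adjusted p = 0.136, or 0.0739 with trends removed).

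The last comparison, aC against FCP, asked whether the αC domain differs from the Der m 1-derived preparation, between groups whose chromosome medians were alike. Inflammatory genes were higher in aC. TNFAIP2 (chromosome 14, 103121469 to 103137439) and SOD2, a mitochondrial superoxide dismutase, each rose by 1.47 ± 0.02 (log2, n = 2 against 2), TNIP1, an inhibitor of NF-kB signalling, by 0.92 ± 0.02, ICAM1 (chromosome 19, 10271120 to 10286615) by 0.85 ± 0.02, the syndecan gene SDC4 by 0.76 ± 0.02 and TNC by 0.89 ± 0.03. SMAD3, a TGF-beta signal transducer, rose by 0.71 ± 0.03 and the cytokine gene LIF by 0.91 ± 0.04. The neutrophil chemokine gene CXCL8 (chromosome 4, 73740569 to 73743716) rose by 1.5 ± 0.09, from a mean of 11.1 to 31.6 CPM, and IL6 by 1 ± 0.14. Among the fallen genes with the smallest p-values, YWHAZ fell by 0.15 ± 0.004, the chaperone genes HSPA5 and HSP90AB1 fell by 0.17 ± 0.003 and 0.14 ± 0.002, the mitochondrial ribosomal RNA RNR1 fell by 0.38 ± 0.02 and IGFBP3 fell by 0.34 ± 0.02. YWHAZ and HSP90AB1 have pseudogenes, so their values are uncertain. The 3 genes changed at least 16-fold all fell: RPL7A_1 (-6.51 ± 0.08), ABR_1 (-4.42 ± 0.51) and MTCH2 (-4.01 ± 0.5). All 3 have annotated copies and are uncertain, and the call of MTCH2 ended without FCP replicate 1 or 2 (-4.15 and -3.85) or aC replicate 1 or 2 (-3.77 and -4.29). The structural RNAs RMRP (-3.2 ± 0.29) and RN7SK (-2.83 ± 0.26) were also lower in aC. These 5 genes were chosen after their values were seen.

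Of the NF-kB and inflammatory targets 29 of 34 rose and 0 fell in aC against FCP (31 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 3.39e-37, and adjusted p = 0.00353 with an estimated correlation). Interferon-stimulated genes rose in 20 of 33 cases with 0 fallen (24 adjusted over the list alone), RIGI by 0.77 ± 0.07 and IRF1 by 0.45 ± 0.04 (camera adjusted p = 5.49e-15, and adjusted p = 0.0114 with an estimated correlation). Heat shock genes fell in 10 of 15 and rose in 1 (11 adjusted over the list alone), HSPH1 by 0.25 ± 0.02 and DNAJB1 by 0.26 ± 0.02 (camera adjusted p = 4.86e-12, and adjusted p = 0.0587 with an estimated correlation). Targets of YAP and serum response factor fell in 11 of 25 and rose in 1 (14 adjusted over the list alone), AXL by 0.15 ± 0.01 (camera adjusted p = 2.47e-07, and adjusted p = 0.0374 with an estimated correlation). Mitochondrially encoded messenger RNAs fell in 11 of 13 (12 adjusted over the list alone), ATP8 by 0.13 ± 0.02 and COX1 by 0.11 ± 0.003 (camera adjusted p = 2.28e-20, and adjusted p = 0.0453 with an estimated correlation).

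**Figure D4:**
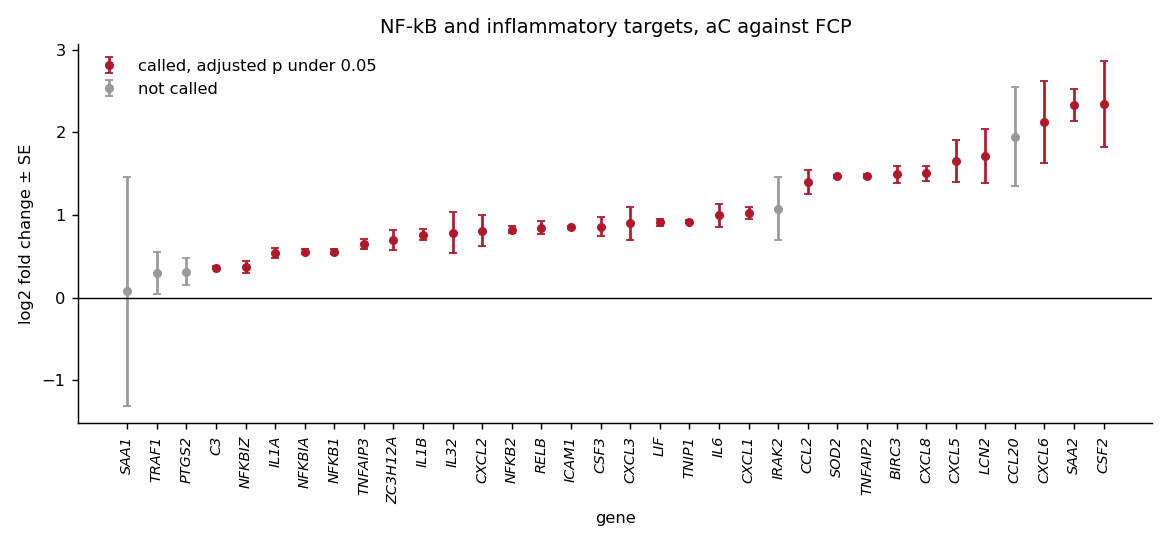
Log2 fold change in aC against FCP (vertical axis) of the 34 tested NF-kB and inflammatory targets (horizontal axis, ordered by fold change). Bars are standard errors derived from the edgeR F statistic (n = 2 libraries per group), red marks genes called and grey those not called. All 34 estimates lie above 0, and 29 were called.

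Adhesion lists differed little between aC and FCP. Desmosome and hemidesmosome genes rose in 5 of 17 cases and fell in 1 (6 adjusted over the list alone), PLEC by 0.08 ± 0.001 and LAMB3 by 0.35 ± 0.02 (camera adjusted p = 0.0254, and adjusted p = 0.135 with an estimated correlation). Adhesion receptors of the immunoglobulin and other families rose in 5 of 17 and fell in 1 (6 adjusted over the list alone), with a median of -0.01 and a mean of 0.07 (camera adjusted p = 0.0311, and adjusted p = 0.135 with an estimated correlation). Extracellular matrix genes rose in 9 of 32 and fell in 5 (19 adjusted over the list alone; camera adjusted p = 0.0311, and adjusted p = 0.135 with an estimated correlation). In the tight junction list CLDN1 alone was called (0.74 ± 0.03, 3 adjusted over the list alone; camera adjusted p = 0.0311, and adjusted p = 0.135 with an estimated correlation). Plasminogen and coagulation genes rose in 6 of 20 and fell in 2 (11 adjusted over the list alone), PLAU by 0.32 ± 0.04 and SERPINE2 by 0.44 ± 0.06 (camera adjusted p = 0.00164, and adjusted p = 0.132 with an estimated correlation). Integrin subunits rose in 4 of 19 and fell in 2 (7 adjusted over the list alone; camera adjusted p = 0.322), ITGAV by 0.22 ± 0.03, and CDH1 was not called (0.03 ± 0.03, adjusted p = 0.709). With trends removed the calls of the desmosome (adjusted p = 0.372), immunoglobulin-family (0.0717) and extracellular matrix (0.303) lists ended and focal adhesion genes were called as lower (0.0173, and adjusted p = 0.134 with an estimated correlation), and with no filter these 3 calls and that of the tight junction list ended (0.085, 0.0508, 0.0664 and 0.0891). Calls also ended for the desmosome list without FCP replicate 1 (0.0808) or aC replicate 2 (0.0779), the immunoglobulin-family list without FCP replicate 1 (0.0935), the extracellular matrix list without FCP replicate 2 (0.0528) or aC replicate 1 (0.0577) and the tight junction list without FCP replicate 2 (0.104).

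The oxidative stress, p53, metallothionein, glucocorticoid and cholesterol lists were also called in aC against FCP, each with adjusted p = 0.135 with an estimated correlation. Oxidative stress and NRF2 targets rose in 5 of 19 cases (6 adjusted over the list alone; camera adjusted p = 0.000276), the ferritin genes FTL and FTH1 by 0.18 ± 0.02 and 0.51 ± 0.05. Targets of p53 rose in 4 of 20 (6 adjusted over the list alone; camera adjusted p = 0.00719), CDKN1A by 0.23 ± 0.02. Metallothioneins rose in 3 of 9 (3 adjusted over the list alone; camera adjusted p = 0.00718), MT1X by 0.19 ± 0.02. Ferritins and metallothioneins have close relatives or pseudogenes, so their values are uncertain. Glucocorticoid targets rose in 5 of 12 and fell in 1 (7 adjusted over the list alone; camera adjusted p = 0.00981), ANGPTL4 by 0.51 ± 0.06. Cholesterol and fatty acid genes fell in 10 of 27 and rose in 2 (12 adjusted over the list alone; camera adjusted p = 0.000214), with a median of -0.06 and a mean of 0.14. In all, 1470 of 16307 genes were called, 745 risen and 725 fallen, of which 50 rose and 15 fell at least 2-fold. The count was 853 to 909 when any one of the 4 libraries was left out, 867 by DESeq2 and 2327 without genes that have copies. Of the 20 preset genes 10 were called (13 adjusted over the list alone), 8 risen and 2 fallen. ITGA5 rose by 0.13 ± 0.04 and ITGB6 by 0.42 ± 0.1, and ITGB1 fell by 0.09 ± 0.01 and FN1 fell by 0.13 ± 0.002. Those not called included ITGA2 (0.08 ± 0.06), ITGB3 (0.22 ± 0.08), CDH2 (-0.05 ± 0.04), CD44 (0.04 ± 0.03), TLR4 (-0.07 ± 0.05), CD14 (-0.02 ± 0.25), PLAUR (0.37 ± 0.12), F2RL1 (0.03 ± 0.14) and CCL20 (1.95 ± 0.6, adjusted p = 0.166), which DESeq2 called. With GC content and length trends removed PLEC turned to -0.05 and ITGA5 (0.11) was not called, nor was ITGA5 by DESeq2. The call of ITGB6 ended without FCP replicate 1 (0.44), FCP replicate 2 (0.39), aC replicate 1 (0.43) or aC replicate 2 (0.4), and that of ITGA5 without FCP replicate 2 (0.08), aC replicate 1 (0.15) or aC replicate 2 (0.11).

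Fold changes against Mock share the Mock libraries, so their overlap was set beside simulated unchanged groups and independent lists. The simulation drew every group at the Mock level, where genes near 0 in Mock can add much noise to fold changes. Simulated values, and differences from them, therefore do not size the part that comes from the shared libraries. FCP and aC rose together at 5670 genes (2313 expected of independent lists) and fell together at 5576 (2159), with 22 genes called in opposite directions. Their fold changes had a correlation across genes of 0.958 (0.663 simulated) and a covariance of 2.401 (0.229 simulated, a difference of 2.172). FBG and FCP rose together at 2778 genes (1471 independent) and fell together at 3331 (1546), with 1071 in opposite directions, a correlation of 0.502 (0.618 simulated) and a covariance of 0.64 (0.227 simulated, a difference of 0.413). For FBG and aC the joint calls were 2723 risen (1498 independent) and 3291 fallen (1572), with 1172 opposite, a correlation of 0.493 (0.621 simulated) and a covariance of 0.645 (0.227 simulated, a difference of 0.418). With 1 Mock library for each treatment, so that no library is shared, the covariances were 2.416 for FCP and aC, 0.581 for FBG and FCP and 0.594 for FBG and aC. These lie closer to the values with shared libraries than the simulation would give. The joint calls were not counted without shared libraries, so part of their excess may come from the shared controls. Spearman correlations of fold changes with GC content were -0.52, -0.34 and -0.31 in FBG, FCP and aC against Mock. Against FBG they were -0.11 in FCP and -0.07 in aC, so a GC trend common to the comparisons with Mock may add to the overlap. Joint calls and covariances were not computed with trends removed.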

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

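Leaving out genes with copies, removing GC content and length trends and thinning to equal depth were chosen only after the results were seen. Of 243 gene fold changes named for the comparisons, 215 kept their side of the threshold and, where called, their direction. The settings were DESeq2 size factors, the DESeq2 Wald test, library size only, the replicate block, trend removal and each left-out library of the comparison. Only settings that gave a value were counted, and a change of sign in a gene called under neither setting was not. The other 28 changed under at least 1 setting, and 6 of the 28 reversed. Trend removal gave no value for ATP8, COX1 and RNR1 in aC against FCP. With trends removed ITGB1 went to -0.2 and TLR4 to -0.25 in FBG against Mock, FN1 to -0.32 in FCP against Mock and PLEC to -0.05 in aC against FCP. With library size only FN1 went to 0.03 in FBG against Mock and ITGA5 to 0.19 in FCP against Mock. Library size only moved the median of all genes by construction, from 0.02 to 0.13 in FBG against Mock and from 0.06 to 0.28 in FCP against Mock, and for the other 4 the cause was not tested.

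Counts of called genes moved with the threshold by construction. At an absolute log2 fold change of at least 1 they were 1125, 4650, 4842, 3379, 3678 and 65 in FBG against Mock, FCP against Mock, aC against Mock, FCP against FBG, aC against FBG and aC against FCP, and at adjusted p under 0.01 the last was 889. In aC against FCP the count was 867 by the DESeq2 Wald test and 2327 without genes that have copies, and the cause was not tested. Leaving out libraries gave 853 to 909 there (865 and 853 without FCP replicates 1 and 2, 909 and 867 without aC replicates 1 and 2), with fewer samples, and at least 52.8% of the genes called with all libraries were kept. The other ranges were 7270 to 7390, 11029 to 11425, 11273 to 11641, 9689 to 10037 and 10042 to 10365, where the lone library is assumed to vary like the other groups. Risen and fallen genes were near equal in number, and the majority also turned with the stricter filter in FBG against Mock (3572 risen and 3465 fallen) and aC against Mock (4231 and 4232), by the DESeq2 Wald test in FCP and aC against Mock (5171 and 5377, 5297 and 5485), at adjusted p under 0.01 in the same pair (5281 and 5417, 5443 and 5522), without Mock replicate 1 (5685 and 5740, 5817 and 5824) and without Mock replicate 2 (5689 and 5710, 5785 and 5803). In aC against FCP it turned with no filter (779 and 931), without genes that have copies (1105 and 1222), with trends removed (596 and 764) and without FCP replicate 2 (409 and 444).

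Lists called with an estimated correlation, which also lowers the degrees of freedom, numbered 0, 0, 5, 5, 5 and 4 in the same order. By fry, which asks another question, they numbered 26, 31, 30, 29, 29 and 24. In FBG against Mock 8 lists were called with no filter and 7 with trends removed over the 30 lists then testable, and 4 to 7 with a library left out (7 without FBG replicate 2, 6 without Mock replicate 1). With trends removed YAP and serum response factor targets (adjusted p = 0.000409, and adjusted p = 0.154 with an estimated correlation) were called as risen there, as were airway markers (0.0494), and oxidative stress targets (0.0429) and metallothioneins (0.0429) as fallen. With an estimated correlation these 3 were at adjusted p = 0.328, 0.524 and 0.309. In aC against FBG the call of heat shock genes ended with trends removed (0.0739) and that of oxidative stress targets without FBG replicate 1 (0.0552). Neither list was called there with an estimated correlation. The cause was not tested.

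Further lists were called only under some settings, at the preset correlation, and the cause was not tested. In FCP against FBG focal adhesion components were called as lower with no filter (0.007), without genes that have copies (0.0176), with trends removed (0.0182), at equal depth (0.0472), and without FBG replicate 1 (0.0378), FBG replicate 2 (0.0433) or FCP replicate 2 (0.0432). Immunoglobulin-family receptors were called as higher there without copies (0.0388), with trends removed (0.0437), at equal depth (0.0454), and without FBG replicate 1 (0.0477) or FCP replicate 1 (0.0414). Histone messenger RNAs were called as higher with no filter (0.01), with trends removed (0.0233) and without FBG replicate 1 (0.0477), and glucocorticoid targets as lower with no filter (0.0169) and with trends removed (0.0397). With trends removed these 4 were at adjusted p = 0.147, 0.168, 0.153 and 0.206 with an estimated correlation. Protocadherins were called as lower and oxidative stress targets as higher with trends removed (0.0397 each, and adjusted p = 0.168 and 0.266 with an estimated correlation), and adherens junction components as higher without copies (0.0176). In aC against FBG the extracellular matrix list was called as lower with no filter (0.0102) and with trends removed (0.000197, and adjusted p = 0.093 with an estimated correlation), glucocorticoid targets as lower with no filter (0.0445) and adherens junction components as higher without copies (0.0244). In aC against Mock glucocorticoid targets were called as lower with no filter (0.0303) and with trends removed (0.0455, and adjusted p = 0.251 with an estimated correlation), heat shock genes with no filter (0.0172), without copies (0.0391) and without Mock replicate 2 (0.0421), and immediate early genes with no filter (0.00983). In FBG against Mock NF-kB targets and oxidative stress targets were called as lower with no filter (0.0145 each), without FBG replicate 2 (0.043 each) and without Mock replicate 1 (0.0437 and 0.0258), and immediate early genes with no filter (0.034). In aC against FCP histone messenger RNAs (7.05e-05) and S phase genes (0.00686) were called as lower with no filter, the latter also without copies (0.043).

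The covariance of fold changes fell to 0.318 (FBG and FCP), 0.317 (FBG and aC) and 1.429 (FCP and aC) under the stricter filter, which tests fewer genes, and was 0.581 for FBG and FCP and 0.594 for FBG and aC with 1 Mock library for each treatment, where no library is shared (2.416 for FCP and aC). With the replicate block the counts of called genes were 8128, 11906, 12130, 10835, 11086 and 1410, and PLAUR (-0.37) in FBG against Mock and ITGB6 (0.42) in aC against FCP were not called. Deviations of libraries with equal numbers had correlations of -0.022 to 0.018, so the numbers were not taken to pair the libraries. Thinning to 15137196 counts per library gave fewer called genes in each comparison, 7967, 11443, 11612, 10344, 10632 and 1282. Changes of 0.25 on the log2 scale were recovered for 34% of 50 such genes in simulated FBG against Mock and 22% of 50 in simulated aC against FCP. These simulations were not repeated, so the shares do not rank the comparisons.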

Other observations

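The 8 tests of explanations in this part, and the genes it names, were chosen only after the results were seen.

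Some regulators known from epithelial cells had many counts in FCP and aC libraries and few in Mock, though no list of such regulators was tested. GRHL2, a transcription factor of epithelial cells, had 0 counts in both Mock libraries together, 12 in FBG, 990 in FCP and 1017 in aC. The epithelial splicing factor ESRP1 was higher in FCP than in Mock by 8.91 ± 0.12 on the log2 scale (edgeR, n = 2 against 2), SOX15 by 4.78 ± 0.13, the protease inhibitor gene SERPINB5 by 6.59 ± 0.1 and the membrane protease gene ST14 by 6.52 ± 0.08. Their Mock counts were 5, 34, 24 and 41 in the same order, and the printed errors lie below the counting error of such counts. The transcription factor gene FOXC2 was lower by -4.25 ± 0.04 and NR2F1 by -4.08 ± 0.07, and the lung transcription factor gene NKX2-1, a member of the airway marker list that went against most other members, had 311 counts in Mock and 331 in FBG against 2 in FCP and 12 in aC.

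Further single genes, picked by their values, were higher in aC than in FCP, and those outside the lists test no inflammatory theme. In the NF-kB list these were the chemokine genes CXCL5 (1.66 ± 0.25) and CCL2 (1.4 ± 0.15), the growth factor gene CSF3 (0.86 ± 0.12) and the acute-phase gene SAA2 (2.33 ± 0.2), and TLR2 (1.07 ± 0.15) was the 1 risen member of the innate receptor list, which was not called (camera adjusted p = 0.194). Outside the lists SGPP2, a sphingosine phosphate phosphatase gene, was higher by 1.56 ± 0.13, the pentraxin gene PTX3 by 1.13 ± 0.14, the receptor gene IL7R by 1.05 ± 0.2, SERPINA3 by 0.9 ± 0.15 and the keratin gene KRT6B by 1.86 ± 0.21. SAA2 and KRT6B have close relatives, so their values are uncertain. Calls that ended were SERPINA3 without FCP replicate 1 or 2 (0.97 and 0.83) or aC replicate 1 or 2 (0.94 and 0.85), KRT6B without FCP replicate 1 or 2 (1.86 in each) or aC replicate 1 (1.79) and IL7R without FCP replicate 2 (0.86). PTX3 and CCL2 were lower in FCP than in Mock, by -2.77 ± 0.14 and -1.81 ± 0.15, and PTX3 stayed lower in aC than in Mock (-1.64 ± 0.13). CCL2 was at -3.53 in FBG against Mock, with 38 counts against 445.

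The FCP and aC libraries stood apart from Mock and FBG, with 531 genes changed at least 16-fold in FCP against Mock and 3, all of them genes with annotated copies, in aC against FCP. A response of scattered genes within 4 h as the whole cause is argued against by the chromosome 9 median of 0.47 in FCP against Mock (0.4 to 0.52), where the largest autosome median in 1000 shuffles of genes was 0.31. GC content, length or depth as the whole cause is argued against by 415 of the 444 such genes still testable after trend removal that stayed at least 16-fold changed and 456 of the 487 still testable after thinning. Cells of another stock or sub-line in the FCP and aC libraries are a candidate explanation. Chromosome 9 medians were 0.47 and 0.46 in FCP and aC against Mock and 0.46 and 0.44 against FBG. In each of these comparisons 95.5% of the 44 chromosome 18 genes up to 14.1 Mb lay above the autosomal median. No autosome median differed by more than 0.02 between aC and FCP or 0.05 between FBG and Mock. The treatment runs along the same division, so a response to FCP or aC on top of it stays open and was not separated here.

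Between FBG and Mock 8226 genes were called. GC content and length as the whole cause is argued against by 652 of the 936 genes changed at least 2-fold and still testable after trend removal that stayed so. RNA of the FCP and aC kind carried into the FBG libraries as the whole cause is argued against by 785 of the 817 genes without annotated copies that were at least 2-fold higher in FBG (96.1%), which rose by more than the highest share of 3.77% would give. A response to fibrinogen stays open, as does any difference between the cultures or library preparations of these groups, which may be part of the pattern and was not tested.

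The NF-kB list was higher in aC than in FCP, between libraries with alike chromosome medians. GC content and length are argued against by a median of 0.86 after trend removal, against 0.88 before. A further step of all genes along the division between FCP and aC and the rest is argued against by the 0.82 left after that axis was removed (quartiles 0.55 and 1.42). The removal used 1 slope of 0.0199 fitted over 11266 genes. It cannot decide on a further step confined to the inflammatory genes, which stays open. Bacterial endotoxin in the aC preparation may be a cause and cannot be told apart from a response to the αC domain, since endotoxin levels are not given in the sources used here. Of the receptor genes LY96 had 3 counts over the 8 libraries, CD14 324 and TLR4 9743, which decides neither.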
